A study of Mus musculus with 10 samples.

How the data were processed

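Peaks of Gli1-FLAG, Sox2, Foxa2 and a mock FLAG precipitation and sequencing tags of H3K4me2 and H3K27ac were analysed as the authors deposited them, with positions on mouse build mm9. HOMER and mm9 are named in the submitters' processing notes, without a version. The aligner, the tag filter, the peak caller, its threshold and the control behind each list are not given in the sources used here. The 6 peak lists, with start and end only, were 2 Gli1 replicate lists, a final Gli1 list whose making is not stated, and 1 list each for Sox2, Foxa2 and mock. The final Gli1 list also carries a whole number from 1 to 841 in line order, a score with no stated meaning in the deposited list, which was read as the authors' rank. The other lists have no height or score, and their line order was used only to describe them in 4 equal parts. In the replicate lists it followed the final rank with a Spearman correlation of 0.93 and 0.89 across shared peaks, which are not independent replicates.

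The histone data were counts of tags per position and strand as deposited by the authors, not scaled and not limited to 1 tag per position, with 1 library per mark and condition per the labels. The libraries held 1.48 to 2.14 tags per occupied position, and tag lengths were 32 bases in all H3K4me2 libraries and 59, 59 and 52 bases in the H3K27ac libraries at 0 h, with RA and with RA and SAG. The top 1% of windows held 46.6 to 53.9% of H3K4me2 tags and 29.2 to 40.0% of H3K27ac tags. Tags from PCR copies are not independent molecules, so all intervals and limits on tag counts cover counting error only. With 0 shared peaks, the upper limit given is 3 counts of the list.

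Each tag was shifted 75 bases along its strand and counted within 1000 bases of each peak centre. Counts were expressed as CPM, the tags scaled to the library total, and compared as log2(CPM + 0.5), a scale that understates changes of weakly marked sites. Medians carry 95% bootstrap intervals over peaks, from 10000 draws, or 2000 for the Sox2 list, and these describe the peaks in the libraries compared. Neighbouring peaks can share tags, whereas the bootstrap and the random splits treat each peak as an independent unit. Upper bounds for the 15 Gli1 peaks with Foxa2 depend on the random seed, since so few peaks leave wide gaps between values. Each median was set against 10000 lists of genome windows of the same number and width, matched on the mean tag level of the mark over its 3 libraries. A peak or window counted as changed when the ratio of CPM was at least 2, its exact binomial interval excluded 1, and 1 of the libraries compared held 20 or more tags. The same rule was run on 1000-base windows of the whole genome, and adjacent changed windows were merged into regions. Distances run from the centre of a region or window to the centre of the nearest peak. Windows near peaks were compared with unchanged and changed windows of the same tag level, drawn 10000 times.

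Peak lists were compared by the number of peaks that share at least 1 base. The one-sided permutation test placed the peaks 100000 times at random on the same chromosomes, with Benjamini-Hochberg adjustment over 7 pairs of lists, and a further 10000 placements were matched on the summed histone tags at 72 h with RA and SAG. Shares carry exact Clopper-Pearson 95% intervals. Differences between Gli1 peaks with and without Sox2 or Foxa2 were set against 10000 random splits of the Gli1 peaks of the same sizes. Samples were grouped by their titles.

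The comparisons, tests, alternatives and the rule for named sites were fixed before the data were examined, and additions are named where they are used. By that rule the named sites are, per mark and comparison, the 10 regions with the largest rise and the 10 with the largest fall whose other mark moved the same way, of which the leading and longest are described. Named too are the 10 highest ranked Gli1 peaks and the Gli1 peaks that meet both Sox2 and Foxa2. Leading Sox2 and Foxa2 peaks were not named, since their lists carry no score. Counts around gene start sites, gene lists and motifs had been planned and were left out, because no mm9 annotation or sequence was used here, and the window rule set beforehand for that case took their place.

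The procedures were tested on simulated data. With tags drawn for the 1182204 H3K27ac windows of the SAG comparison, 1.03% of unchanged windows and 10% of windows with a fold of 1.5, 96% with a fold of 3 and 98% with a fold of 4 were called. For the 297295 H3K4me2 windows the shares were 1.16%, 16%, 92% and 98%. Each fold was planted in only 50 windows per mark, so the shares called at a fold are coarse. These draws held counting error only, without PCR copies or differences between cultures, so they do not give the rate of false calls in these data. The overlap count found 50 of 50 planted overlaps, its test gave a p under 0.05 in 4 of 200 runs with no overlap, and 3 of 100 unshifted lists fell outside the middle 95% of matched lists. Alternatives covered the overlap rule, list strength, each Gli1 replicate alone, window width, 1 tag per position, scaling, pseudocount, tag shift, sex chromosomes and tag minimum. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.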

Results

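The series followed mouse embryonic stem cells as they were turned into neuralized embryoid bodies, free-floating aggregates that take on a neural fate. After 2 days in suspension the aggregates were sampled (0 h) or induced for 3 days (72 h) with 500 nM all-trans retinoic acid (RA), a signal that gives neural tissue a posterior character. Some cultures also received SAG, a small molecule that switches on the Hedgehog receptor component Smoothened and so stands in for the ventralizing signal Sonic hedgehog, at 50 to 800 nM. Which sample got which dose within this range is not stated, so samples with SAG may differ in dose. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) located 3 transcription factors in cultures with RA and SAG. These were FLAG-tagged Gli1, the zinc-finger effector of Hedgehog signalling, Sox2, the HMG-box factor of neural progenitors, and Foxa2, the forkhead factor of the floor plate. A mock FLAG precipitation from the parental line, which carries no FLAG tag, was the background. The Gli1, Foxa2 and mock samples each held 2 biological replicates, and the Sox2 sample was a single sample as far as the labels say.

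H3K4me2, found at promoters and enhancers, and H3K27ac, found at active ones, were profiled at 0 h, at 72 h with RA and at 72 h with RA and SAG, with 1 library per mark and condition. The H3K4me2 libraries held 40518562, 53294822 and 55889512 tags in that order, and the H3K27ac libraries held 109234566, 106420666 and 85652760. Differences between histone libraries therefore have no replicate check, no p-value is given for them, and intervals on them cover counting error or the spread of peaks only. No 72 h culture without RA was analysed here, so changes from 0 h to 72 h with RA, called changes with RA below, hold 3 days of culture as well as RA. Changes with SAG compare parallel cultures at 72 h, with RA and SAG against RA alone, and are not a later step in time. Levels are given as CPM, the tags scaled to the library total. Regions are named by mm9 position, since no gene annotation or sequence of that build was used here.

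Gli1 bound a set of sites that both biological replicates found. The replicate lists held 1593 and 1070 peaks, with median widths of 211 and 229 bases, and 783 of the 1070 peaks of replicate 2 (73.2%, exact 95% interval 70.4 to 75.8%) shared a base with a peak of replicate 1. Random placement on the same chromosomes gave a mean of 0.332 shared peaks, and placement in windows with the same histone tags gave 3.43. Agreement was highest at the top of the lists. In replicate 2, 98.5% of the first and 41.6% of the last of 4 equal parts of the list met a replicate 1 peak, and in replicate 1 the shares ran from 86.7% to 25.6%. The authors' final ranked list held 841 Gli1 peaks, of which all 841 shared a base with replicate 1 and 790 with replicate 2, while the other 51 lay a median of 316800 bases from the nearest replicate 2 peak. The mock precipitation gave 73 peaks, and 0 of the 841 Gli1 peaks met them, which allows a share of up to 0.357%. The replicate overlap had a one-sided permutation p of 1e-05 (adjusted p = 1.75e-05 over 7 pairs of lists), the smallest that 100000 placements can give. That p describes the lists, in which each peak is a unit, and where peaks are called against a mock sample an absence of shared mock peaks is built in.

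Gli1 and Sox2 met at a minority of sites, and far more often than chance. Of the 841 Gli1 peaks, 76 shared a base with 1 of the 3048 Sox2 peaks (9.04%, interval 7.19 to 11.2%), against 0.507 expected at random and 7.78 in windows with the same histone tags. Foxa2, whose list held 176 peaks, met 15 Gli1 peaks (1.78%, 1.00 to 2.92%), against 0.033 and 0.212 expected, and 1.12% of the peaks of Gli1 replicate 2. Sox2 peaks met 18 of the 176 Foxa2 peaks (10.2%, 6.17 to 15.7%), against 0.0924 and 0.794. Only 2 Gli1 peaks met both other factors. They lay on chromosome 2 at 147702456 to 147702684 (rank 30 of the Gli1 list) and on chromosome 13 at 81778636 to 81778871 (rank 241). None of the 3048 Sox2 or 176 Foxa2 peaks met a mock peak, which allows shares of up to 0.0984% and 1.70%. Each of the 3 overlaps between factors had a one-sided permutation p of 1e-05, adjusted to 1.75e-05, and of 0.0001, adjusted to 0.000175, against matched windows, the smallest possible in both cases. The control behind each list is not given in the sources used here, and lists called against the same control share part of their chance values.

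**Figure D1:**
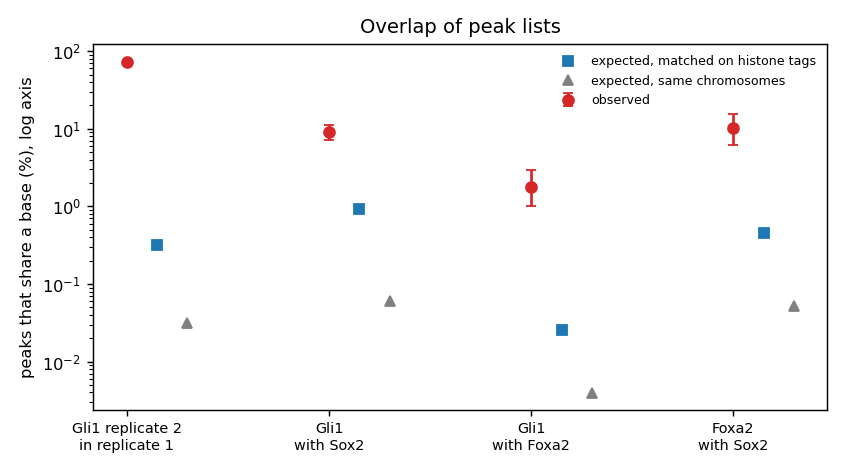
Share of peaks (percent, log axis) that share a base with a peak of another list, with exact 95% intervals (red), beside the mean of random placements on the same chromosomes (grey) and in windows with the same histone tags (blue). The observed shares, 73.2% for the Gli1 replicates, 9.04% for Gli1 with Sox2, 1.78% for Gli1 with Foxa2 and 10.2% for Foxa2 with Sox2, lie above both means.

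The 3 days with RA were accompanied by a broad gain of both marks at sites that Sox2 occupied at 72 h. Over the 3048 Sox2 peaks the median log2 change from 0 h to 72 h with RA was 0.82 for H3K27ac (bootstrap interval 0.76 to 0.89) and 0.59 for H3K4me2 (0.55 to 0.63), above all 10000 lists of windows with the same tag level, whose medians reached -0.15 and 0.05. H3K27ac was at least 2 times higher at 1540 Sox2 peaks (50.5%) and lower at 236 (7.74%). The share of Sox2 peaks above the 95th percentile of the genome in H3K27ac went from 53.5% at 0 h to 84.2% with RA. The mean H3K27ac level of Sox2 peaks rose less, from 12.7 to 14.6 CPM. At the 841 Gli1 peaks gains and losses were about equal in number. Their mean H3K27ac fell from 7.97 to 5.67 CPM and the upper quartile from 6.37 to 4.26. Across the genome the top 1% of windows also held less of the H3K27ac tags with RA (29.2%) than at 0 h (40.0%). That share is taken over the top windows of each library, so it does not show that the same sites fell. The upper quartile of H3K27ac rose with RA at Sox2 peaks, from 13.7 to 18.3 CPM, and at Foxa2 peaks, from 1.77 to 2.68. The replicate lists differed here, with H3K27ac higher at 376 and lower at 264 peaks of Gli1 replicate 1 (median 0.15, percentile 99.98 of the matched lists) and at 194 and 194 peaks of replicate 2 (median -0.03, percentile 2.6). H3K4me2 was higher at 343 and lower at 292 peaks of replicate 1 and at 181 and 199 of replicate 2. In the final list the median H3K27ac change was 0.06 (-0.00 to 0.15), at percentile 45.3 of the matched lists, with 180 peaks higher and 165 lower, and for H3K4me2 it was 0.05 (-0.02 to 0.11), at percentile 98.7 of the matched lists, with 168 higher and 184 lower. Foxa2 sites held little of either mark at 0 h, with median H3K4me2 of 0.358 CPM, and had changes of 0.46 (0.41 to 0.57) in H3K4me2 and 0.39 (0.31 to 0.54) in H3K27ac. Matched lists reached 0.16 in H3K4me2. In H3K27ac they had a median of 0.17 and reached 0.38, so the H3K27ac change of Foxa2 sites barely exceeded them. Gli1 peaks outside the Sox2 list and Sox2 peaks outside the Gli1 list differed by -0.80 in median H3K27ac change, beyond all 10000 random splits of these peaks (-0.26 to 0.30). All of these peaks were called at 72 h with RA and SAG, so sites marked at 72 h may be favoured by the choice of lists. The matched windows do not share that choice, and the lists may differ in strictness. A gain with RA and this choice of sites therefore cannot be told apart.

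Scaling by the median ratio of windows instead of total tags shifts log2 ratios between RA and 0 h by 0.29 for H3K4me2 and -0.33 for H3K27ac. Under it the Sox2 medians were 0.85 and 0.56, the Gli1 medians 0.21 and -0.13 and the Foxa2 medians 0.57 and 0.20. A pseudocount of 2 CPM in place of 0.5 gave 0.17 for H3K4me2 and 0.20 for H3K27ac at Foxa2 peaks and 0.53 for H3K27ac at Sox2 peaks, while a pseudocount of 0.1 gave 0.89 and 0.59 at Foxa2 peaks.

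Across the genome, more windows differed between 0 h and 72 h with RA than between the 72 h cultures with and without SAG. Of 1194120 windows of 1000 bases with enough H3K27ac tags, 347174 were higher with RA and 97250 lower, so 78.1% of changed windows were higher, or 58.7% under median ratio scaling. The median 2-kb window of the genome held 0.201 CPM of H3K27ac at 0 h, 0.301 with RA and 0.292 with SAG. At this depth the minimum of 20 tags lies near that background, so many windows counted hold little mark. A gain of marked sites therefore cannot be told apart here from a higher background in the RA library. Counting 1 tag per position left 150253 higher and 84739 lower. For H3K4me2 60182 windows were higher and 86597 lower (41.0% higher, and 54.0% under median ratio scaling, which turns the balance, as do a ratio of 4 and no minimum of tags). Windows that counted as changed in both marks mostly moved the same way. Of these, 36141 were higher in both and 33671 lower in both, while 276 were higher in H3K4me2 and lower in H3K27ac and 1332 the reverse. Most windows higher in H3K27ac did not count as higher in H3K4me2, since 36141 of 347174 did. Of the 60182 windows higher in H3K4me2, the same 36141 counted as higher in H3K27ac. Enough H3K4me2 tags were present in 297482 windows. The region with the largest H3K27ac gain, among those whose H3K4me2 moved the same way, lay on chromosome 2 at 74566001 to 74593000. There CPM went from 8.94 to 386 (log2 change 5.36, ratio 43.2, counting interval 40.5 to 46.0) and was 351 in the culture with SAG. Gains with RA were nearly as large, and levels in the culture with SAG varied, on chromosome 15 at 102842001 to 102880000 (10.8 to 374, and 380 with SAG), chromosome 11 at 96441001 to 96461000 (5.48 to 183, and 240 with SAG) and chromosome 6 at 52142001 to 52153000 (4.87 to 164, and 91.9 with SAG). A region on chromosome 13 at 79007001 to 79014000 went from 1.05 to 54.2, and a region on chromosome 16 at 63497001 to 63508000 from 1.04 to 52.7, of which most was lost again with SAG. All 10 named regions of largest H3K27ac gain lay within 10 kb of a Sox2 peak, and 0 of them within 10 kb of a Gli1 peak. Of the 10 regions of largest H3K27ac loss 1 lay within 10 kb of a Sox2 peak and 0 within 10 kb of a Gli1 or Foxa2 peak. On chromosome 13 at 16920001 to 16925000 H3K27ac fell by 5.23 on the log2 scale, from 89.0 to 1.88, and on chromosome 15 at 65748001 to 65762000 from 101 to 3.99. On chromosome 2 at 153464001 to 153472000 both marks were lost, H3K27ac from 94.5 to 3.67 and H3K4me2 from 42.2 to 2.87. Ranked by H3K4me2, the largest gain was on chromosome 1 at 43415001 to 43420000, from 0.420 to 23.9, in a region that holds a Sox2 peak. The longest was the 20 kb region on chromosome 18 at 84235001 to 84255000, from 5.36 to 126. H3K27ac rose in both regions too, from 1.785 to 45.8 and from 6.42 to 151.

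Adding SAG was accompanied by more of both marks at Gli1 peaks, and the peaks that changed were nearly all higher. With SAG the median H3K27ac level over the 841 Gli1 peaks was 3.08 CPM against 1.94 with RA alone and 1.74 at 0 h. The mean over these Gli1 peaks, which strongly marked sites dominate, was 8.16 CPM with SAG against 5.67 with RA alone, near the 7.97 at 0 h. The median log2 change from RA alone was 0.29 (bootstrap interval 0.26 to 0.35), and the 10000 lists of windows with the same tag level had medians from -0.09 to 0.01. H3K27ac was at least 2 times higher at 210 Gli1 peaks and lower at 8. For H3K4me2 the median change was 0.14 (0.11 to 0.17), matched lists reached 0.01, and 156 peaks were higher and 13 lower. Both marks were higher at 111 Gli1 peaks and at least 1 mark at 255 (30.3%), both were lower at 2, and 0 peaks moved in opposite directions. The share of Gli1 peaks above the 95th percentile of the genome in H3K27ac went from 45.0% to 60.6%. With a pseudocount of 2 CPM the Gli1 medians were 0.18 for H3K27ac and 0.09 for H3K4me2.

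**Figure D2:**
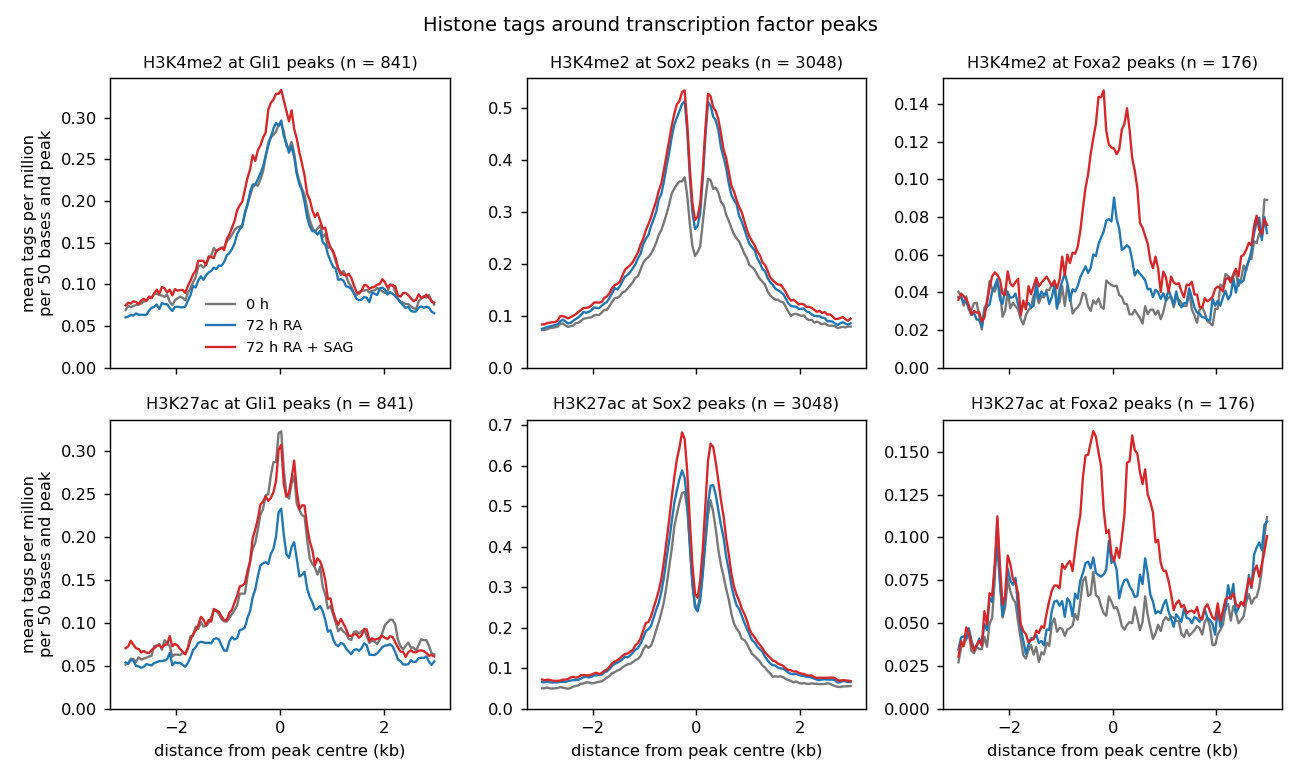
Mean CPM per 50 bases and peak (y axis) against distance from the peak centre in kb (x axis) for H3K4me2 (top) and H3K27ac (bottom) at the 841 Gli1, 3048 Sox2 and 176 Foxa2 peaks, with 1 line per library: 0 h (grey), 72 h RA (blue), 72 h RA and SAG (red). The gain from grey to blue is clearest in H3K4me2 at Sox2 peaks, whose H3K27ac lines nearly meet at the centre, and the gain from blue to red in H3K4me2 is clearest at Foxa2 peaks.

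Foxa2 sites gained most from SAG in H3K4me2, and Sox2 sites least. The median H3K4me2 change over the 176 Foxa2 peaks was 0.69 (0.60 to 0.84), with 89 peaks higher and 1 lower, and the level went from 0.844 to 2.06 CPM. Their median H3K27ac change was 0.40 (0.31 to 0.47), with 56 higher and 2 lower. Over the 3048 Sox2 peaks the medians were 0.05 (0.04 to 0.06) and 0.16 (0.14 to 0.18), and the changed peaks split both ways, 408 higher and 278 lower in H3K27ac. Medians of peaks outside the other list differed by 0.68 in H3K4me2 between Foxa2 and Sox2 (random splits -0.08 to 0.08) and by 0.55 between Foxa2 and Gli1 (-0.17 to 0.22). Gli1 exceeded Sox2 by 0.12 in H3K27ac (-0.09 to 0.08), whereas the 0.10 by which Foxa2 exceeded Gli1 in H3K27ac was within random splits (-0.16 to 0.23). These differences between lists were chosen after the data were examined. A pseudocount of 2 lowered the Foxa2 medians to 0.42 and 0.24, and median ratio scaling raised the Sox2 H3K4me2 median to 0.12. All 3 lists come from cultures with SAG, so sites bound only without it are not among them.

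**Figure D3:**
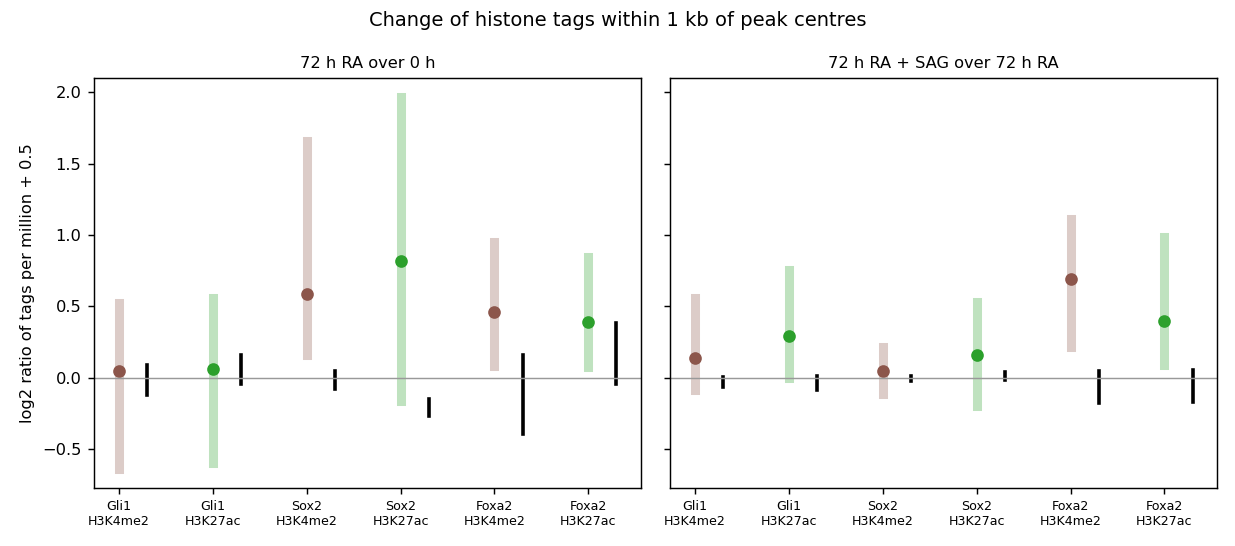
Median log2 ratio of CPM + 0.5 within 1 kb of peak centres (points, with pale bars from the first to the last quartile of peaks) for RA over 0 h (left) and RA and SAG over RA (right), beside the range of medians of 10000 lists of windows with the same tag level (black bars). At Gli1 peaks the medians lie within the black bars on the left and above them on the right (0.14 and 0.29), and at Foxa2 peaks the H3K4me2 median on the right is 0.69.

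Windows with more H3K27ac with SAG lay near Gli1 and Foxa2 peaks more often than windows with the same tags. In H3K27ac 65565 windows were higher with SAG and 101416 lower of 1182204, and in H3K4me2 26988 were higher and 33923 lower of 297295, where median ratio scaling turns the balance (44.3% higher, and 51.5% under that scaling). Both marks were higher in 7574 windows and lower in 5416. Of the windows higher in H3K27ac, 1492 lay within 10 kb of a Gli1 peak, 2.45 times the mean of windows with the same tags, and of the lower windows 602 did, 0.774 times that mean. The corresponding factors for Foxa2 were 2.34 and 1.04, and for Sox2 1.53 and 1.48. The mock factors were 1.96 and 1.02, from 27 and 20 windows. Neighbouring windows are not independent, so these are descriptions without a test. Counting 1 tag per position left 27284 higher and 31608 lower windows in H3K27ac and 13101 and 18591 in H3K4me2.

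The largest SAG gain of H3K27ac was a 17 kb region on chromosome 5 at 102082001 to 102099000, which went from 4.50 to 179 CPM (log2 change 5.17, ratio 39.8, counting interval 36.3 to 43.6) and lay 536 kb from the nearest Gli1 peak. A pair of regions nearby, at 101924001 to 101929000 and 101946001 to 101955000, went from 1.43 to 34.2 and from 4.18 to 60.3. Regions holding Gli1 peaks included chromosome 12 at 57706001 to 57724000 (6.92 to 132), chromosome 2 at 147004001 to 147022000 (9.47 to 159) and chromosome 2 at 147845001 to 147875000 (15.2 to 174), with Gli1 peaks 0.298, 0.068 and 2.69 kb from their centres. Chromosome 5 at 67483001 to 67497000 (12.2 to 152) and 67612001 to 67628000 (13.7 to 169) rose with no Gli1 peak within 100 kb. Of the 10 named regions of largest gain 3 lay within 10 kb of a Gli1 peak and 6 within 10 kb of a Sox2 peak. Of the 10 regions of largest loss 0 lay within 10 kb of a Gli1 peak and 7 within 10 kb of a Sox2 peak. In all 10 of them the level with RA was above that at 0 h, though the RA library enters both ratios. Chromosome 4 at 21605001 to 21619000 held 11.3 at 0 h, 107 with RA and 5.56 with RA and SAG, so that it was lower with SAG by 4.16 on the log2 scale. In the same order, chromosome 1 at 78160001 to 78175000 held 3.45, 84.0 and 4.32, and chromosome 4 at 153836001 to 153850000 held 7.96, 70.8 and 5.23. For H3K4me2, SAG gains included chromosome 13 at 63670001 to 63673000, which holds the Gli1 peak of rank 12, from 8.16 to 59.9, and chromosome 8 at 12609001 to 12611000, which holds a Foxa2 peak, from 1.39 to 12.2. The largest H3K4me2 loss was on chromosome 8 at 8219001 to 8221000, from 4.48 to 0.215.

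**Figure D4:**
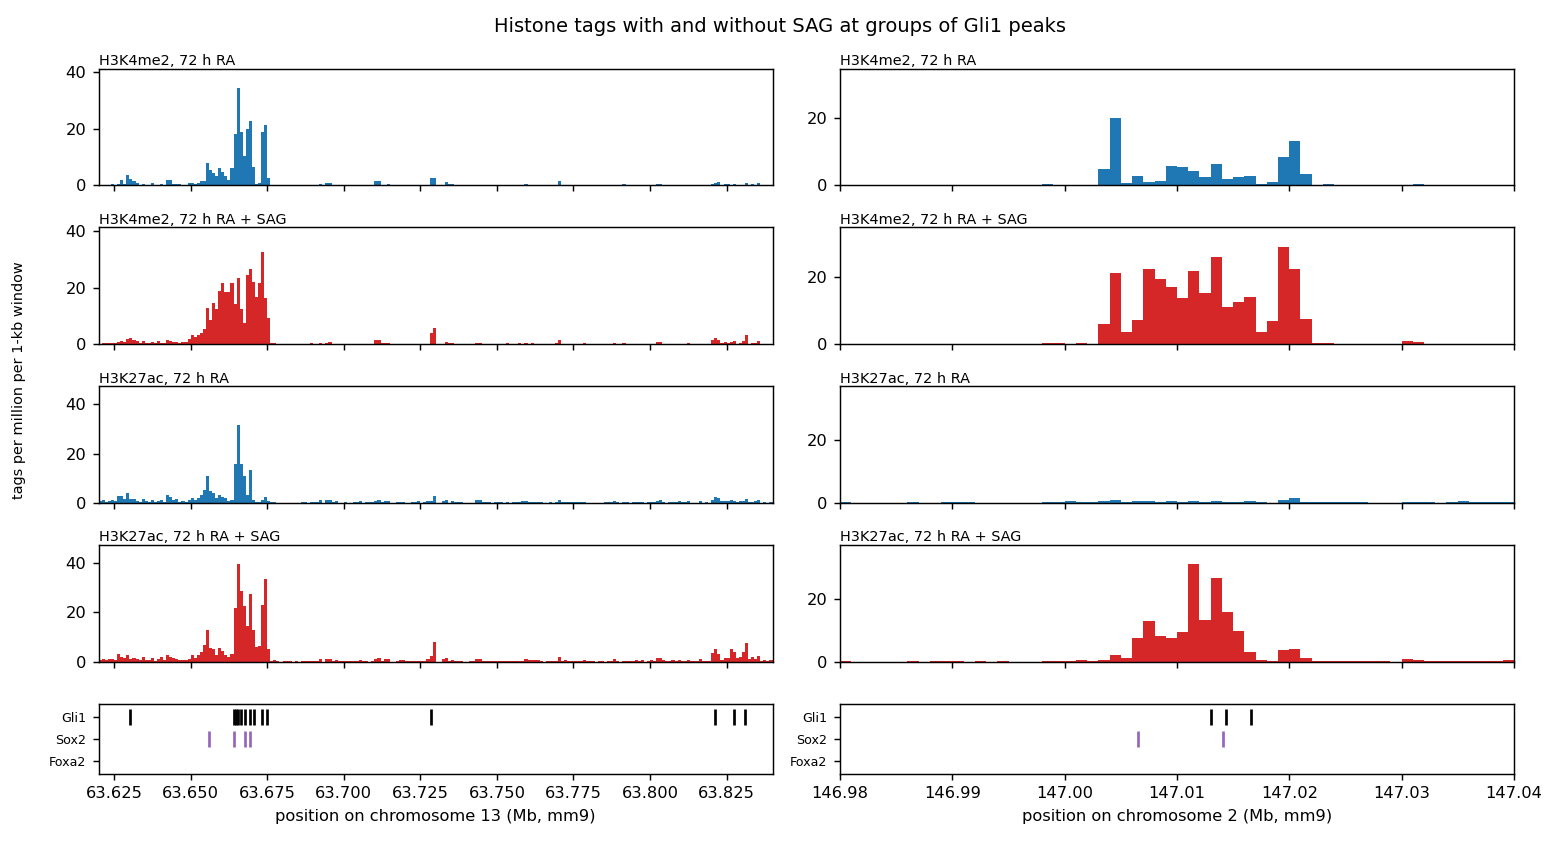
CPM per 1-kb window (y axis) of H3K4me2 and H3K27ac with RA (blue) and with RA and SAG (red) along chromosome 13 (left) and chromosome 2 (right), position in Mb (mm9) on the x axis, above ticks for Gli1, Sox2 and Foxa2 peaks. The chromosome 2 region from 147004001 to 147022000 holds 3 Gli1 peaks and goes from 9.47 to 159 CPM in H3K27ac.

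Gli1 sites that also carried Sox2 had a larger H3K27ac gain with SAG. The 76 Gli1 peaks with Sox2 had a median log2 change of 1.22 (bootstrap interval 0.81 to 1.49) and the 765 without Sox2 of 0.27 (0.23 to 0.30). The difference of 0.95 was beyond all 10000 random splits of the Gli1 peaks (-0.29 to 0.42). H3K27ac was at least 2 times higher at 44 of the 76 (57.9%) and at 166 of the 765 (21.7%). The groups had like H3K27ac levels at 0 h, with medians of 1.67 and 1.75 CPM, though H3K4me2 was already higher with Sox2 (2.84 against 1.88). In H3K27ac they parted to 2.97 and 1.82 with RA and to 10.0 and 2.67 with RA and SAG. For H3K4me2 the SAG changes were 0.37 and 0.12 (difference 0.25, random splits -0.18 to 0.32, percentile 99.9), and this difference was 0.08 in the list of replicate 2 alone and 0.14 in that of replicate 1. With RA alone the peaks with Sox2 had changes of 0.65 in H3K27ac and 0.54 in H3K4me2, against 0.03 and 0.00 in those without, and both differences lay beyond all random splits. In the list of replicate 2 alone these differences were 0.33 for H3K27ac and 0.22 for H3K4me2. Against peaks without Sox2 drawn at the same tag level, a comparison added after the data were examined, the difference in H3K27ac with SAG was 0.94. Without that matching, the difference in the list of replicate 2 alone was 0.54. The tag level was the mean over the 3 libraries of the mark, that with SAG included. Sox2 was mapped only with RA and SAG, so the split may favour sites marked there. Rank was not matched either. Sox2 met 12.8% of the first and 7.62% of the last of 4 equal parts of the Gli1 list by rank, whose median H3K27ac changes with SAG were 0.53 and 0.20.

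Foxa2 split the Gli1 peaks less clearly. The 15 Gli1 peaks with Foxa2 had a median H3K4me2 change with SAG of 0.73 (0.09 to 1.14) against 0.13 (0.11 to 0.17) for the other 826, at percentile 99.9 of random splits. In H3K27ac the medians were 0.55 (-0.07 to 1.31) and 0.29 (0.26 to 0.35), at percentile 89.2, a difference that was not resolved with 15 peaks.

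**Figure D5:**
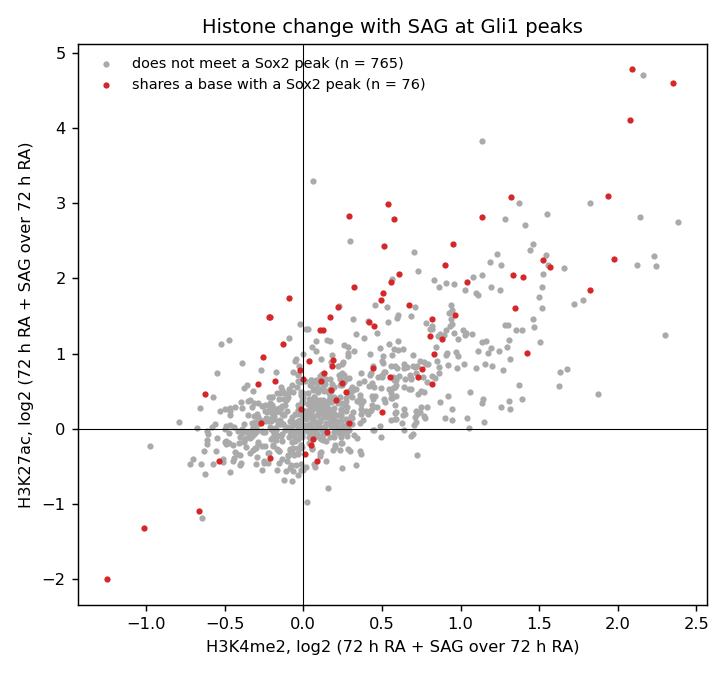
Log2 change with SAG in H3K4me2 (x axis) and H3K27ac (y axis) within 1 kb of the centre of each of the 841 Gli1 peaks, red for the 76 that share a base with a Sox2 peak and grey for the 765 that do not. Red points lie higher, with a median H3K27ac change of 1.22 against 0.27.

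The top-ranked Gli1 peaks differed widely in their marks. The peak of rank 1, on chromosome 19 at 27005153 to 27005362, had little of either mark in cultures without SAG. In H3K27ac it held 0.874 CPM with RA alone and 9.14 with SAG (log2 change 2.81, ratio 10.5, counting interval 8.43 to 13.1), and in H3K4me2 0.694 and 4.78. The peak of rank 2, on chromosome 7 at 146485424 to 146485617, had a change of 0.37 in H3K27ac and did not count as changed. The peak of rank 3, on chromosome 13 at 63667643 to 63667870, shared a base with Sox2 and went from 13.8 to 35.0. The peak of rank 4, on chromosome 19 at 24700467 to 24700560, stayed almost unmarked, with 0.348 and 0.339 CPM. The peak of rank 10, on chromosome 2 at 146746466 to 146746713, held 13.7 at 0 h, 2.40 with RA alone and 10.7 with RA and SAG. Of the 10 highest ranked, 6 counted as higher in H3K27ac with SAG and 0 as lower. Both peaks that met Sox2 and Foxa2 were higher, the rank 30 peak from 2.83 to 17.4 and the rank 241 peak from 1.31 to 5.14. By rank, the median H3K27ac change was 0.53 (0.42 to 0.67) in the first of 4 equal parts of the Gli1 list, 0.35 (0.26 to 0.46) in the next, 0.18 (0.13 to 0.24) in the third and 0.20 (0.10 to 0.29) in the last. Sox2 was met by 27, 19, 14 and 16 peaks of these parts.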

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

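Both tests in this part were set before their results were seen. Peaks of a single Gli1 replicate that the authors' final list leaves out met Sox2 as often as final peaks did. Above, these peaks entered only the overlap of the replicates and the values for each replicate list alone. Of 724 such peaks of replicate 1, 70 shared a base with a Sox2 peak (9.67%, exact interval 7.62 to 12.1%), and of 269 of replicate 2, 24 did (8.92%, 5.80 to 13.0%), whereas 0 of 73 mock peaks did, which allows up to 4.11%. These peaks also had more H3K27ac with SAG, by a median log2 change of 0.21 (0.18 to 0.25) in replicate 1 and 0.14 (0.08 to 0.17) in replicate 2, below the 0.29 of the final list.

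That any window with so much histone marking meets Sox2 this often is argued against by the count itself, since 94 of the 993 peaks met Sox2, 10.6 times the mean of 8.84 in windows with the same histone tags and above the highest of 1000 random sets, 20. The share over both replicates, 9.47% (7.72 to 11.5%), lies within the interval of the final list (7.19 to 11.2%), so as far as Sox2 goes these peaks may be weaker sites of the same kind. Foxa2 was met by 8 of the 724 and 0 of the 269, against 15 of the 841 final peaks, which leans the other way for replicate 2 on few counts and was not tested. A background shared by the Gli1 and Sox2 lists, if they were called against the same control, stays open. No biological difference between the replicates is named in the labels, and none was tested.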

How the results depend on the processing

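The comparison at the same tag level and all alternatives for Foxa2 with RA were chosen after the data were examined, as was the restriction to final peaks found in both replicates, which gave 0.32 for H3K27ac with SAG. No median whose interval excludes 0 changed sign, but both medians of Gli1 peaks with RA, whose intervals hold 0, did, H3K4me2 to -0.00137 with a minimum of 20 tags. All 24 alternatives of the 5 overlaps kept their side of the test threshold, with 8.32 to 11.8% of Gli1 peaks meeting Sox2 and 1.12 to 2.38% meeting Foxa2, lowest in replicate 2 alone. Of 122 alternatives for medians at peaks 43 left the interval of the value reported, of 76 for Gli1 peaks with minus without Sox2 3 did, and of 56 for window counts 26 moved by more than 1.5 times. Unless given below, the cause was not tested.

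Median ratio scaling gave H3K4me2 medians of 0.21 (RA) and 0.20 (SAG) at Gli1, 0.85 and 0.12 at Sox2 and 0.57 (RA) at Foxa2 peaks, and H3K27ac medians of -0.13 (RA) at Gli1, 0.56 and 0.20 at Sox2 and 0.20 (RA) at Foxa2 peaks. A pseudocount of 2 gave H3K4me2 medians of 0.086 (SAG) at Gli1, 0.45 (RA) at Sox2 and 0.17 and 0.42 at Foxa2 peaks, and H3K27ac medians of 0.18 (SAG) at Gli1, 0.53 and 0.13 at Sox2 and 0.20 and 0.24 at Foxa2 peaks. It also brought the difference in H3K4me2 level with and without Sox2 to 1.10. A pseudocount of 0.1 gave H3K4me2 medians of 0.65 (RA) at Sox2 and 0.89 and 0.96 at Foxa2 peaks, and H3K27ac medians of 0.38 (SAG) at Gli1, 0.97 (RA) at Sox2 and 0.59 and 0.48 at Foxa2 peaks. By construction a larger pseudocount shrinks changes of weakly marked sites.

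With 1 tag per position the H3K27ac median was -0.0147 at Gli1 peaks (RA) and 0.67 and 0.13 at Sox2 peaks, and the Sox2 H3K4me2 medians were 0.53 and 0.0702. Within 500 bases the Sox2 medians with RA were 0.64 (H3K4me2) and 0.72 (H3K27ac). Within 2000 bases the H3K4me2 medians were 0.11 (SAG) at Gli1, 0.54 (RA) at Sox2 and 0.59 (SAG) at Foxa2 peaks, and the Sox2 H3K27ac medians 0.74 and 0.13. A minimum of 20 tags gave 0.64 for Foxa2 H3K4me2 with RA. With each Gli1 replicate list alone the Gli1 medians ran from 0.0887 to 0.12 (H3K4me2, RA), 0.0944 to 0.10 (H3K4me2, SAG), -0.0349 to 0.15 (H3K27ac, RA) and 0.26 to 0.26 (H3K27ac, SAG), and the difference with and without Sox2 in H3K27ac with SAG from 0.54 to 0.69. That in H3K4me2 with SAG ran from 0.08 to 0.14, below the 0.25 of the final list, and with RA the differences ran from 0.22 to 0.63 (H3K4me2) and 0.33 to 0.67 (H3K27ac). At the same tag level the H3K27ac difference with RA was 0.91.

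With 1 tag per position 27284 windows were higher and 31608 lower in H3K27ac with SAG, 150253 higher in H3K27ac with RA, and 13101 higher and 18591 lower in H3K4me2 with SAG. A minimum of 50 tags left 22469 and 35368 (H3K27ac, SAG), 144316 higher (H3K27ac, RA), 7969 and 7361 (H3K4me2, SAG) and 20363 and 46286 (H3K4me2, RA). No minimum gave 106680 higher (H3K27ac, SAG), 74075 and 99199 (H3K4me2, SAG) and 148966 and 125711 (H3K4me2, RA). A ratio of 4 left 7973 and 13478 (H3K27ac, SAG), 78675 and 28070 (H3K27ac, RA), 6211 and 6369 (H3K4me2, SAG) and 33473 and 28536 (H3K4me2, RA). Median ratio scaling gave 214945 higher and 151287 lower in H3K27ac with RA. The balance of higher and lower H3K4me2 windows thus turned with a minimum of 50 tags for SAG, and with no minimum or a ratio of 4 for RA, besides median ratio scaling for both. Stricter minimums and ratios leave fewer windows by construction.

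Removing peaks that touch a mock peak removed 0 peaks, and the pseudocount does not enter the window counts. The stronger peaks of the list alone were not run for the Gli1 replicates or for Sox2 with Foxa2, whose lists have no rank, and alternatives for genes, gene lists, start sites and motifs were not run. No paired analysis was possible because each histone group is 1 library.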

Other observations

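The tests of clonal tags, library scaling, peak choice, chromosome copies and grouping in this part were chosen after the results were seen, and so were the named peaks of largest rise. Most Gli1 peaks stood alone, and a small share lay in dense groups. Joining peaks less than 100 kb apart gave 740 groups, of which 15 held at least 3 peaks and together 66 of the 841 (7.85%), whereas 10000 random placements had a mean of 3.20 peaks in such groups and a highest of 20. In windows with the same histone tags the mean was 17.7 and the highest of 1000 random sets 46, so marked chromatin accounts for part of the excess over uniform placement. The largest group, 14 Gli1 peaks on chromosome 13 from 63629814 to 63831261, held the peak of rank 3 and 9 peaks with higher H3K27ac with SAG, and had a median log2 change of 1.34. The next, 8 peaks on chromosome 13 from 64002701 to 64210164, had a median of 0.69. The 3 peaks on chromosome 2 from 147012717 to 147016696 all rose, with a median of 4.71, and so did the 4 from 146659886 to 146785235 (2.16) and the 3 on chromosome 12 from 57621451 to 57722464 (3.10). Groups without such a rise existed too, as the 3 peaks on chromosome 8 from 87941546 to 88049656 had a median of -0.53 and those on chromosome 3 from 34633969 to 34657084 of -0.11. The peaks with the largest rises were those of rank 21 on chromosome 2 at 147013891 to 147014798, from 0.968 to 39.8 CPM, of rank 742 beside it at 147012717 to 147013420, from 0.996 to 38.6, and of rank 110 on chromosome 12 at 57714717 to 57715881, from 0.545 to 24.8. The rank 21 and rank 742 peaks belong to the group of 3 on chromosome 2 above. Their counting windows of 1000 bases on each side overlap, so these rises share tags.

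Among Gli1 peaks grouped by their H3K27ac change with RA, those higher with RA than at 0 h were most often higher still in the culture with SAG. Of the 180 Gli1 peaks higher with RA, 64 were also higher with SAG than with RA alone (35.6%), against 44.9 for independent changes, and of the 165 lower with RA 27 were (16.4%), against 41.2. Of the 496 not changed with RA, 119 were higher with SAG (24.0%). The RA library enters both changes, which by chance alone favours peaks lower with RA and higher with SAG. Counting error alone, drawn for unchanged peaks, gave at most 1 such peak in 100 simulations. These draws held no PCR copies or differences between libraries, so they cannot weigh the effect of the shared library. Gli1 peaks above the 95th percentile of the genome in H3K27ac neither at 0 h nor with RA numbered 386, and 123 of these were higher with SAG (31.9%), against 39 of the 290 above it at both times (13.4%).

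The gain of H3K27ac at Gli1 peaks with SAG is a difference between 2 single libraries, whose tags are 59 bases long with RA and 52 with SAG, and an effect of tag length on the positions that can be mapped was not tested. Clonal tags are argued against, since counting 1 tag per position left the median at 0.30 (0.25 to 0.35), and so is library scaling, since median ratio scaling gave 0.34 (0.29 to 0.38). Peaks were called only in cultures with SAG, and sites picked there may lean towards it. Sox2 peaks, picked in the same kind of culture, gained less, by 0.12 (random relabelling -0.09 to 0.08), but the lists may differ in strictness, so this choice of sites and an effect of SAG cannot be told apart. Gli1 binding without SAG was not analysed here.

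Sox2 peaks were more frequent on chromosomes 8 and 14, with 288 and 219 peaks, 1.90 and 1.52 times what their length gives, a pair picked from these counts. Chromosome 11 came close with 208 peaks, 1.48 times. More marked chromatin there is argued against, since the 507 peaks were 1.77 times the mean of windows with the same histone tags and above the highest of 1000 random sets, 340. Background tag density in the histone libraries was 0.83 to 0.89 times the autosome median on chromosome 14, which gives no sign of extra copies there. On chromosome 8 the density was 1.08 to 1.12 times. It was not corrected for the positions that can be mapped or set against cells of known copy number. An extra copy in part of the cells therefore stays open for both chromosomes. Gli1 and Foxa2 peaks were also more frequent on chromosome 8 (1.41 and 1.37 times by length) but not on chromosome 14 (0.63 and 0.48). Extra copies in the Sox2 culture alone may remain. The share of Sox2 peaks on chromosomes 8 and 14 was 14.4 to 18.8% in each of 4 equal parts of the list. This cannot decide the question, since the list has no score and its order need not follow strength. Without the Sox2 tags extra copies cannot be told apart from a preference of Sox2. No biological explanation was tested. On chromosome Y, 30 Sox2 peaks (8.97 times by length) and 5 mock peaks were called, and 0 Gli1 peaks.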
